A study of Mus musculus with 7 samples.

How the data were processed

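Plasma cells of mice were sorted as Gr1-, CD3-, IgD- and CD138+ cells into wells of multi-well plates, with further gates for the antibody class on the cell, per the labels. CD138 is syndecan-1, the usual surface marker of plasma cells, and Gr1, CD3 and IgD mark myeloid cells, T cells and naive B cells. Lymph node cells also had to bind the hapten NP and carry a lambda1 light chain. They were thus sorted as specific for the immunogen NP-KLH, and they were taken 5 or 14 days after a primary immunization. Spleen cells were taken at steady state. RNA of each cell was read as a targeted library of about 500 transcripts with unique molecular identifiers (UMIs), which label each captured molecule so that copies made by PCR are counted as 1 molecule.

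The authors deposited raw counts, as UMIs per gene and cell, in 1 table per tissue with cells in rows. Per the submitters' processing notes, bcl2fastq, Bowtie2 2.2.9 and HTSeq were used with the genome build GRCm38.p6. The filters that gave these cells and the strand setting are not given in the sources used here. The deposited columns also gave the gate, day, mouse and plate of every cell, and these were used as deposited. The lymph node table held 1336 cells and 509 genes, and the spleen table held 949 cells and 499 genes, of which 497 genes were in both. Of the 511 genes in either table, 505 matched a RefSeq symbol of GRCm38.p6, 4 matched a synonym and 2 did not match. A blank cell in place of a count occurred 1 time and was taken as 0. No cells had identical counts, no cell was removed, and no doublet caller was run because cells were sorted singly.

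Each of the 7 GEO samples was an experiment that held several plates, with 1 mouse in spleen experiment 3 and 2 to 4 mice in the others. Mice gave unlike shares of the gates. In spleen experiment 1, mouse 1 gave 63 IgM and 6 IgG2b cells, and mouse 4 gave 34 and 40. Sums per experiment thus do not pair gates by mouse, and differences between mice are mixed with those between gates. The design fixed earlier had taken a sample for a single plate. The experiment was kept as the unit, and sums per mouse and per sort plate were added as alternatives. Some mice were spread over more than 1 plate, so sums per sort plate can count a mouse more than once and are not independent replicates. Counts were summed over the cells of an experiment and gate, with at least 10 cells per sum. Heavy chain constant genes define the gates, so they were left out of library sizes and tests. These genes were absent from the spleen table, so the gates could be compared with the counts only in lymph node. IgG2a and IgG2b cells of lymph node were pooled as IgG2a/b, as fixed in the design. The labels do not state whether the experiments were independent, so p-values measure only the spread between these samples.

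Sums were compared with the quasi-likelihood test of edgeR 4.0.16 (filterByExpr, TMM normalization, R 4.3.3) with the experiment as a block and Benjamini-Hochberg adjustment over the genes tested. The threshold was an adjusted p of 0.05. All plasma cell gates of a tissue, without naive cells, entered 1 fit for the comparisons between antibody classes, which left 4 residual degrees of freedom in spleen and 2 in lymph node. The block was checked by the correlation of deviations from the gate means. It lay between 0.284 and 0.606 for the 9 pairs of spleen sums from the same experiment and between -0.438 and 0.137 for the 18 pairs from different ones. In lymph node it lay between 0.228 and 0.351 for 3 pairs of the same experiment and between -0.293 and 0.0733 for 6 pairs of different ones. Levels are given as UMIs per 10000 UMIs, as the mean and SD over experiments with equal weight. A fold change is the fitted log2 ratio, the first group over the second. Its standard error (SE) is approximate. It was taken as the size of the log2 fold change over the square root of the F statistic of the edgeR test.

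Gene lists were fixed with the groups, tests, alternatives and the rule for named genes before the data were examined. They covered plasma cell identity, mature B cell identity, germinal centre, migration and adhesion, mucosal IgA-associated genes, type 1 and interferon response, type 2 associated genes, unfolded protein response and secretion, cell cycle, survival and apoptosis, inhibitory receptors and checkpoints, cytokines and cytokine receptors, Toll-like and innate sensing, transcriptional regulators of switching and fate, heavy chain constant genes, and markers of T cells, myeloid cells and granulocytes, NK and innate lymphoid cells, and erythroid and stromal cells. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, and again with an estimated correlation. Counts of members past the threshold are given over all genes tested and adjusted over the list alone.

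Genes were drawn for naming, per tested comparison, from Prdm1, Xbp1, Irf4 and Sdc1 with the heavy chain genes, the 10 largest changes in each direction among passing genes with at least 0.1 UMI per cell in either group, and up to 4 members with the smallest p of each list with at least 3 tested members. Where under 5 genes passed, the 10 with the smallest p were used and said not to pass. In comparisons without a test, the 10 largest ratios of UMIs per cell in each direction were named among genes with at least 0.5 UMI per cell in either group. All day 5 cells came from 1 experiment, so comparisons that use them have no test over experiments; their intervals are exact Poisson intervals at 95% and cover counting error only. A group with no UMI was set at a floor of 3 counts over the group, and a fold against it is a lower bound.

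The steps were tested on simulated counts with 200 changed genes, where 337 were tested for IgM against IgA and about 427 for IgG1 against IgG2a/b. This share is far above that of the genes called between antibody classes below. A high share eases the adjusted threshold, so the rates of changed genes found may be too high for these data. For IgM against IgA in spleen, 25.2% of genes changed by 2-fold and 81.0% of those changed by 4-fold were found, with 1.78% of unchanged genes called. For IgG2b against IgA these values were 24.2%, 71.2% and 1.65%, for IgM against IgG2b 25.0%, 82.3% and 1.37%, and for IgG1 against IgG2a/b in lymph node 23.8%, 72.7% and 0.860%. For IgA against IgM and IgG2b together they were 39.2%, 86.4% and 2.19%, and for spleen plasma cells against naive cells 29.7%, 75.8% and 1.04%. The simulated fit over the day 5 mice found 16.3% and 64.7% and called 1.17%. A list made of changed genes was called in 5 of 5 simulations of each comparison and a list of unchanged genes in 0. Simulated genes were drawn independently of each other, so this does not show how the list test acts on correlated genes.

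Alternatives were DESeq2 1.42.0, limma on mean log2 values, library size without TMM, no filter on low counts, genes above 5% of all UMIs left out, at least 20 cells per sum, cells with few UMIs left out, no replicate block, only the groups compared, IgG2b without IgG2a, and each experiment left out in turn. Comparisons of IgA with IgM and IgG2b together, of plasma cells with naive cells, of day 5 isotypes over mice, and of the tissues were added after the data were seen, as were sums per mouse and per sort plate, fits that kept naive cells, and ratios without the IgG2b cells of day 5 mouse 1. Comparisons that need IgM cells of day 14 were not analysed here, because the table marked no cell as such. Tables were handled with Python 3.11.15 and pandas 2.3.3.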

Results

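Counts of 2285 sorted cells were compared, 1336 from lymph node and 949 from spleen. Spleen held 276 IgA, 303 IgM, 220 IgG2b and 150 naive cells from 9 mice in 3 experiments. Lymph node on day 14 held 290 IgG1, 227 IgG2a, 291 IgG2b and 78 naive cells, and on day 5 it held 109 IgM, 84 IgG2a, 184 IgG2b and 73 naive cells, in all from 9 mice in 4 experiments. Spleen experiments 1, 2 and 3 held 213555, 187984 and 150597 UMIs, with medians of 348, 328 and 372 UMIs per cell. Day 14 lymph node experiments 1 and 2 held 546635 and 41480 UMIs, the day 5 experiment 384387, and the experiment labelled with both days 243056, with medians of 835, 295, 523 and 562 UMIs per cell. All cells of the last were marked as day 14. Naive cells had fewer UMIs than plasma cells, with a median of 218.5 per cell in spleen against 369.5, 452 and 434 in IgA, IgM and IgG2b cells. H2-K1 took 13.5% and Mzb1 12.8% of all spleen UMIs, and 15.2% and 12.1% of those in lymph node.

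Heavy chain constant genes followed the sort gates in lymph node on day 14. Ighg1 was counted at 26.2 UMIs per 100 cells in the IgG1 gate, against 0 in the IgG2a gate and 0.344 in the IgG2b gate. Ighg2c, the gene that encodes the IgG2a-type chain in some mouse strains, was at 30.4 UMIs per 100 cells in the IgG2a gate, and Ighg2b was at 53.6 in the IgG2b gate. Iglc1, the lambda1 light chain of the sort, was at 187, 206 and 201 UMIs per 100 cells in these gates and at 0 in 78 naive cells. On day 5 the IgG2b gate held 28 Ighg1 UMIs beside 27 Ighg2b UMIs in 184 cells. In its mouse 1, with 141 of these cells, Ighg1 was at 19.1 and Ighg2b at 8.51 UMIs per 100 cells, so the gene of the gate was not the highest there, and in mouse 2 they were at 2.33 and 34.9. These cells are part of the day 5 IgG2a/b group in the comparisons below. The IgM gate of day 5 held only 4 Ighm UMIs beside 4 of Ighg2c in 109 cells, too few to check that gate by its heavy chain. The near-identical constant genes can share reads, so their counts are uncertain at this level. Of the light chain genes, Iglc1 was at 41.3 and the kappa gene Igkc at 51.4 UMIs per 100 cells in that gate. They were at 58.3 and 1.19 in the day 5 IgG2a gate and at 42.9 and 22.3 in the IgG2b gate. The lambda1 gene of the sort was thus not the highest light chain gene in the IgM gate.

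**Figure D1:**
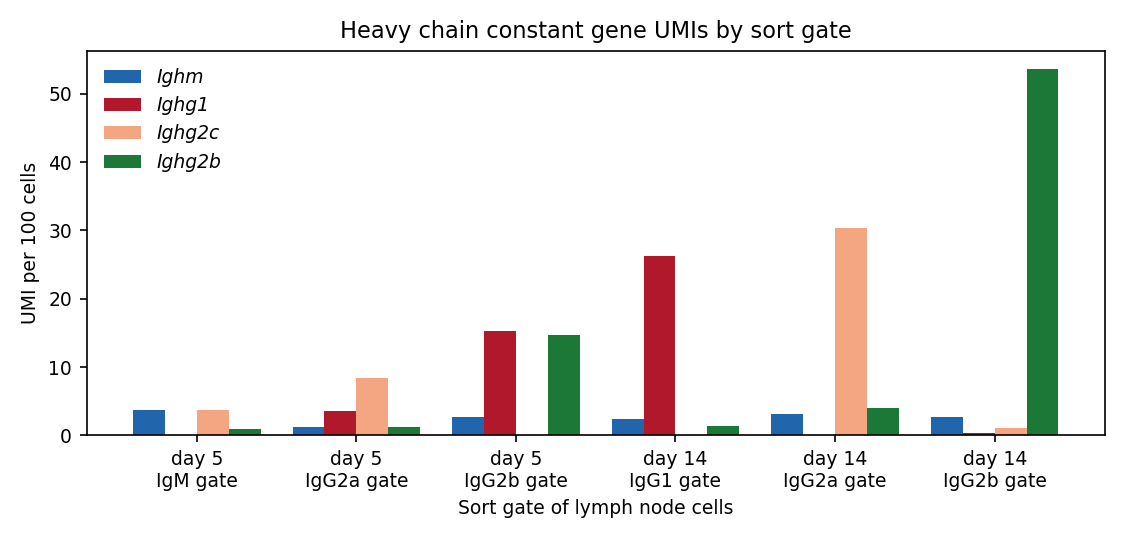
UMIs of heavy chain constant genes per 100 lymph node cells (vertical axis) by day and sort gate (horizontal axis), bars pooled over cells with no replicate error. On day 14 each IgG gate had its own gene highest, at 26.2, 30.4 and 53.6, and on day 5 the IgG2b gate held Ighg1 at 15.2 and Ighg2b at 14.7.

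Plasma cells of spleen had more of several plasma cell genes and less of several mature B cell genes than naive cells, a comparison added after the data were seen. Xbp1, a transcription factor of the secretory pathway, was at 120 ± 51.3 UMIs per 10000 in plasma cells and 5.62 ± 2.17 in naive cells (SD, n = 3; log2 fold change 4.57, SE 0.31). Prdm1, which encodes Blimp-1, the factor that drives plasma cell differentiation, rose by 4.66 on the log2 scale, Irf4 by 1.73 and Sdc1, which encodes CD138, by 3.13. Plasma cells were sorted by CD138, so the rise of Sdc1 is not independent of the sort. Ly6c1 rose by 6.08 and Mzb1, a chaperone of antibody assembly, by 3.78. Pax5, the factor of B cell identity, fell by 5.14 on the log2 scale, H2-Aa of MHC class II by 3.61, the follicle homing receptor Cxcr5 by 3.59, Cd72 by 7.08 and the lymph node homing receptor Sell by 5.25. Slpi had 972 UMIs in plasma cells and 0 in naive cells, at least 23.5-fold higher against a floor of 3 counts over the group.

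Of 359 genes tested, 59 rose and 50 fell (edgeR). Of 18 tested members of the plasma cell identity list, 10 rose, 1 fell and 7 did not pass, with 11 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.64e-07, and adjusted p = 0.125 with an estimated correlation). Of 29 mature B cell members 1 rose, 16 fell and 12 did not pass, with 2 higher and 16 lower adjusted over the list alone (camera adjusted p = 1.56e-08, and adjusted p = 0.183 with an estimated correlation). In the unfolded protein response list 4 of 11 members rose, Xbp1, Edem1, Bhlha15 and Ern1, and 6 adjusted over the list alone (camera adjusted p = 0.0179, and adjusted p = 0.183 with an estimated correlation). Of markers of other cell types, Lck fell among 11 T cell genes (by 1.07 on the log2 scale, not passing adjusted over the list alone) and Il1rl1 among 3 NK genes (by 2.82), while none of 4 myeloid and 2 erythroid or stromal genes passed. Cell cycle members Ccnd2, Top2a, Mki67 and Aurkb rose among 10 tested, as they did adjusted over the list alone, without a list call (camera adjusted p = 0.181). The count was 56 without experiment 1 and 62 without experiment 2. With library size alone all genes moved by a median of -0.19 on the log2 scale, and all 109 genes kept their direction.

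**Figure D2:**
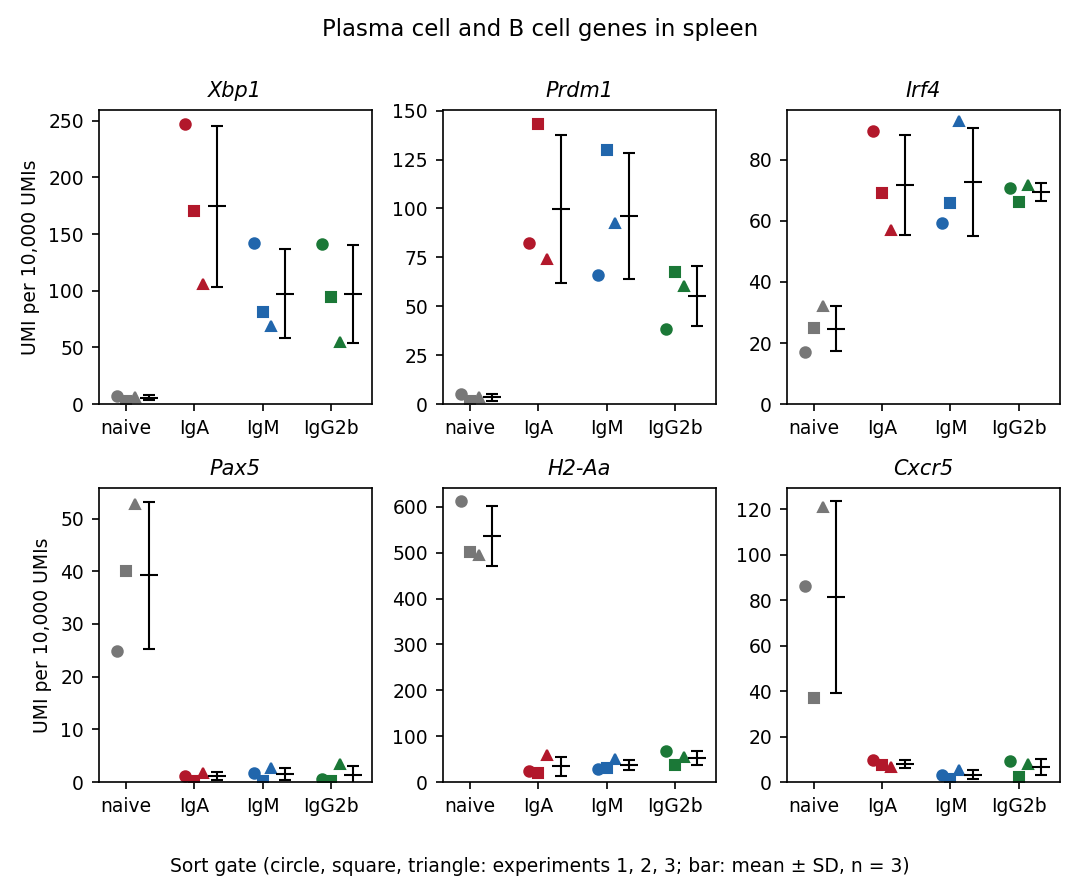
UMIs per 10000 UMIs (vertical axes) of 6 genes in naive cells and in 3 plasma cell gates of spleen (horizontal axes). Points are experiments and bars the mean and SD (n = 3); in all 3 experiments Xbp1, Prdm1 and Irf4 lay higher, and Pax5, H2-Aa and Cxcr5 lower, in plasma cells as a group than in naive cells.

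IgM and IgA plasma cells of spleen were compared to ask how cells of these classes differ in expression. IgM cells had more H2-K1, a classical MHC class I heavy chain, at 1679 ± 449 against 754 ± 243 UMIs per 10000 (SD, n = 3; log2 fold change 1.38, SE 0.15, edgeR adjusted p = 0.00666). H2-DMa, a subunit of the peptide exchange factor for MHC class II, was at 72.0 ± 4.88 against 36.5 ± 7.21 (log2 fold change 1.20, SE 0.20), and Ly6c1, a plasma cell surface protein, at 107 ± 13.2 against 52.2 ± 17.8 (1.27, SE 0.18). IgM cells had less Tmem176b, a membrane protein gene, at 25.9 ± 17.3 against 162 ± 72.6 (log2 fold change -2.67, SE 0.39, edgeR adjusted p = 0.0143). The galectin-1 gene Lgals1 was at 142 ± 0.583 against 363 ± 57.9 (log2 fold change -1.15, SE 0.22), and Runx2, a runt-domain transcription factor, at 5.70 ± 4.79 against 35.9 ± 13.0 (log2 fold change -2.70, SE 0.55, edgeR adjusted p = 0.0464).

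Of 354 genes tested, 7 were higher and 4 lower in IgM cells, each in 3 of 3 experiments. Besides those named, Ltbp3, which binds latent TGF-beta (log2 fold change 1.43), the kinase gene Txk (1.69), the cytokine gene Il1a (1.33) and the endocytic receptor gene Ly75 (1.13) were higher, and Lsp1, an actin-binding protein of leukocytes, was lower (log2 fold change -1.02). The plasma cell regulators did not pass, at log2 fold changes of -0.62 for Xbp1 (edgeR adjusted p = 0.107), 0.22 for Irf4, 0.15 for Prdm1 and -0.15 for Sdc1. Xbp1 passed as lower with library size alone (log2 fold change -0.82, edgeR adjusted p = 0.0450), over sums per mouse (-0.76, edgeR adjusted p = 0.0341), with DESeq2 and over sums per sort plate. Among 18 plasma cell identity genes Ly6c1 passed, also adjusted over the list alone, and among 47 cytokine and receptor genes Il1a, with Il23a (log2 fold change 2.21) adjusted over the list alone. Among 20 mucosal IgA-associated genes Runx2 was lower, and adjusted over the list alone also Ccr9, the gut homing receptor (log2 fold change -1.25), and Tgfbr1 (-1.56). Among 4 tested myeloid markers none passed with edgeR over all genes; adjusted over the list alone the integrin gene Itgam was lower (log2 fold change -2.71, SE 0.61). This marker of myeloid cells was counted in cells gated as Gr1-, CD3-, IgD- and CD138+, with 18 UMIs in IgM and 117 in IgA cells. No list was called (smallest camera adjusted p = 0.730). The count of 11 was 1 without experiment 1, 0 without experiment 2, 1 without experiment 3, 0 without the experiment block and 1 with only these gates in the fit, while DESeq2 called 35, limma 6 and sums per mouse 20, where Ly6c1 did not pass (edgeR adjusted p = 0.115). With library size alone 5 genes were higher and 7 lower, since all genes moved by a median of -0.20 on the log2 scale; all 11 genes kept their direction, and Il1a and Ly75 did not pass (edgeR adjusted p = 0.0501 each). In that scaling 1 plasma cell identity gene was higher and 1 lower, and 0 cytokine and receptor genes passed.

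Among genes that passed between IgG2b and IgA cells of spleen, the largest fold change was that of Tnfrsf17, which encodes BCMA, the receptor through which plasma cells take survival signals. It was at 1.85 ± 1.06 UMIs per 10000 in IgG2b cells against 42.0 ± 20.2 in IgA cells (SD, n = 3; log2 fold change -4.22, SE 0.44, edgeR adjusted p = 0.00546). Tmem176b was at 18.2 ± 12.3 against 162 ± 72.6 (log2 fold change -3.17, SE 0.40), and Ly6d, a surface protein of the B lineage, at 7.96 ± 3.50 against 36.0 ± 6.77. IgG2b cells had more Cxcr3, the receptor for interferon-induced chemokines, at 30.2 ± 9.88 against 8.81 ± 3.47 (log2 fold change 1.99, SE 0.34), more H2-K1 at 1378 ± 240 against 754 ± 243 (1.13, SE 0.15), and more of the proliferation marker Mki67 at 80.4 ± 6.48 against 32.5 ± 18.1 (1.59, SE 0.35). Over sums per mouse neither Cxcr3 (edgeR adjusted p = 0.0822) nor Mki67 (0.143) passed, and Mki67 did not pass with library size alone either (0.0739).

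Of 354 genes, 11 were higher and 9 lower in IgG2b cells, each in 3 of 3 experiments. Also higher were H2-DMa (log2 fold change 1.42), the pyruvate carrier gene Mpc2 (1.08), Ltbp3 (1.27), Ly75 (1.06), Cd24a (1.33), Il23a (2.28), Il1a (1.03) and Tnfsf9 (0.91). Also lower were Ccr7 (log2 fold change -2.54), the shared cytokine receptor chain Il2rg (-1.95), Cd69 (-1.75), the B cell receptor subunit Cd79a (-1.02), Runx2 (-2.66) and the coactivator gene Pou2af1 (-0.65). Of 18 plasma cell identity genes Tnfrsf17, Ly6d and Pou2af1 were lower and 15 did not pass, with 1 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.0488, and adjusted p = 0.630 with an estimated correlation). Of 10 cell cycle genes Mki67 was higher, also adjusted over the list alone (camera adjusted p = 0.0455, and adjusted p = 0.695 with an estimated correlation). Of 47 cytokine and receptor genes Il23a, Il1a and Tnfsf9 were higher and Il2rg lower, with 3 higher and 2 lower adjusted over the list alone. Xbp1 (log2 fold change -0.66), Prdm1 (-0.62), Sdc1 (-0.37) and Irf4 (0.17) did not pass. Xbp1 passed as lower with library size alone (log2 fold change -0.86, edgeR adjusted p = 0.0271), over sums per mouse (-0.70, edgeR adjusted p = 0.0474) and over sums per sort plate, and both Xbp1 and Prdm1 did with DESeq2. Of 4 myeloid genes none passed with edgeR over all genes; adjusted over the list alone Itgam, S100a9 and S100a8 were lower and Flt3 higher. S100a8, a granulocyte gene, had 3 UMIs in IgG2b cells and 226 in IgA cells, which had been gated as Gr1-. The count of 20 was 5 without experiment 1, 0 without experiment 2, 5 without experiment 3, 1 without the experiment block and 2 with only these gates, while DESeq2 called 55, limma 23 and sums per mouse 27, where Cd69 (edgeR adjusted p = 0.0614), Cd79a (0.0677) and Mpc2 (0.0907) did not pass either and Il23a was not tested. With library size alone 7 genes were higher and 14 lower, all 20 genes kept their direction, and Ly75 (edgeR adjusted p = 0.0584), Il1a (0.103) and Tnfsf9 (0.0739) did not pass. In that scaling 5 plasma cell identity genes were lower, 0 cell cycle genes passed, and 1 cytokine and receptor gene was higher and 2 lower.

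IgM cells of spleen had more Ly6d, Tnfrsf17 and Cd79a than IgG2b cells and less Cxcr3 and Mcm2. Ly6d was at 52.9 ± 10.6 UMIs per 10000 against 7.96 ± 3.50 (SD, n = 3; log2 fold change 2.77, SE 0.32), Tnfrsf17 at 18.6 ± 1.83 against 1.85 ± 1.06 (3.34, SE 0.43) and Cd79a at 226 ± 75.8 against 75.8 ± 21.8 (1.55, SE 0.20), each with an edgeR adjusted p of 0.00752. Cxcr3 was at 4.23 ± 1.43 against 30.2 ± 9.88 (log2 fold change -2.78, SE 0.36), and Mcm2, a subunit of the replicative helicase, at 8.10 ± 2.44 against 42.7 ± 5.51 (-2.39, SE 0.41). Ly6c1 was also higher (log2 fold change 1.11, SE 0.18).

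These 6 of 354 genes passed, 4 higher and 2 lower, each in 3 of 3 experiments. Of 18 plasma cell identity genes Ly6d, Tnfrsf17 and Ly6c1 were higher, and Pou2af1 and Prdm1 too adjusted over the list alone (camera adjusted p = 0.000388, and adjusted p = 0.173 with an estimated correlation). Of 10 cell cycle genes Mcm2 was lower, also adjusted over the list alone (camera adjusted p = 0.000134, and adjusted p = 0.618 with an estimated correlation). Xbp1 (log2 fold change 0.03), Irf4 (0.05) and Sdc1 (0.22) did not pass, and Prdm1 passed over all genes with DESeq2 alone. Sums per mouse called 4 genes, of which 2 were among the 6, and Cxcr3 (edgeR adjusted p = 0.175), Cd79a (0.0926), Ly6c1 (0.387) and Mcm2 (0.228) did not pass there. Ly6c1 did not pass with library size alone either (edgeR adjusted p = 0.0563). The count was 3 without experiment 1, 0 without experiment 2, 4 without experiment 3 and 0 without the experiment block, while DESeq2 called 21 and limma 4.

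**Figure D3:**
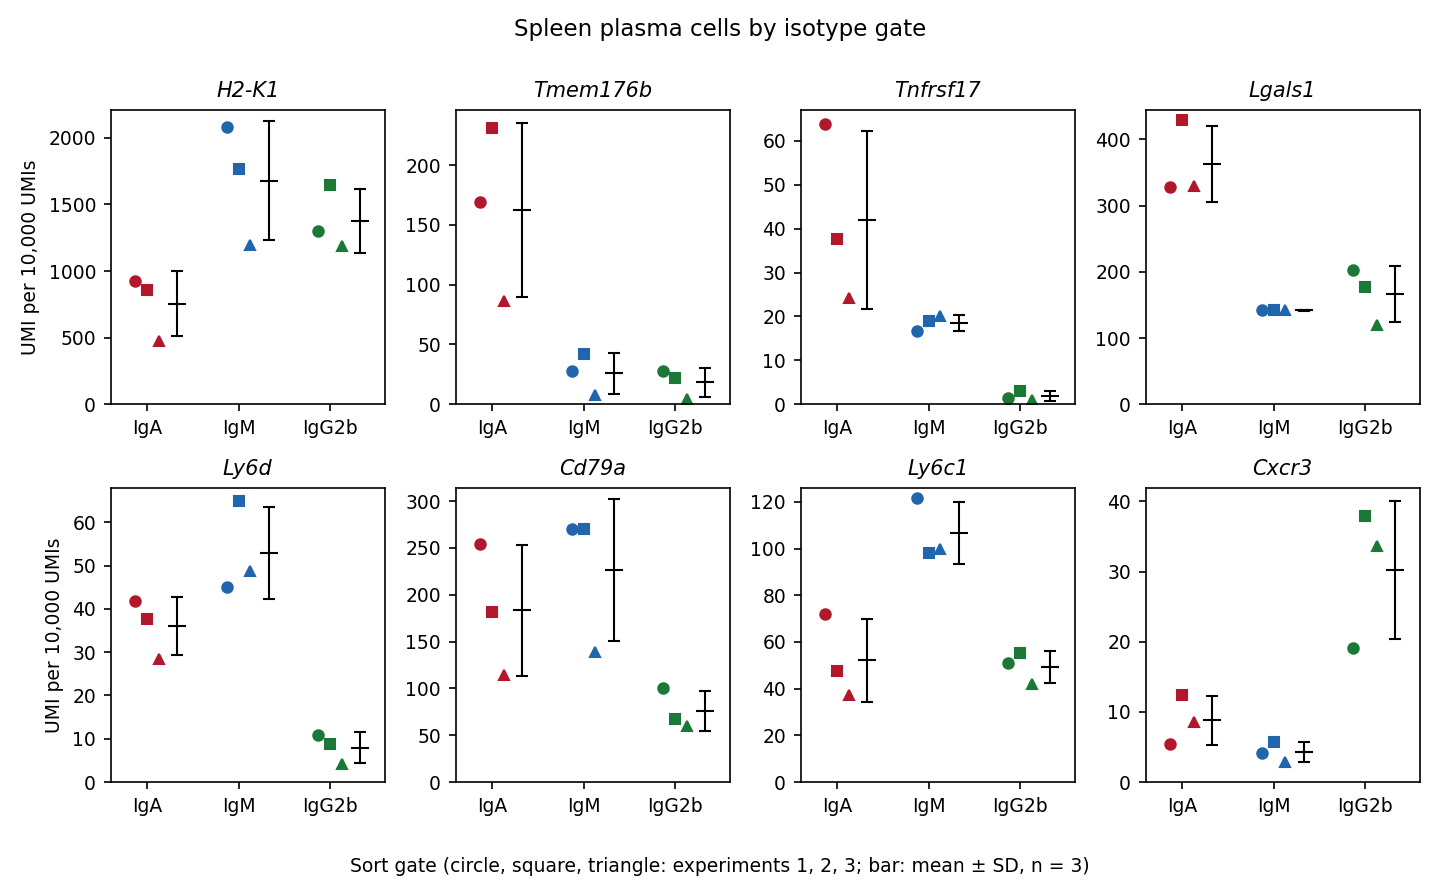
UMIs per 10000 UMIs (vertical axes) of 8 genes in IgA, IgM and IgG2b plasma cells of spleen (horizontal axes). Points are experiments and bars the mean and SD (n = 3); Tmem176b lay at a mean of 162 in IgA cells against 25.9 and 18.2, and Tnfrsf17 at 1.85 in IgG2b cells against 42.0 and 18.6.

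IgA cells were also compared with the mean of IgM and IgG2b cells, a comparison added after the data were seen. A gene can pass in it through 1 of these gates alone. IgA cells had more Tmem176b, at 162 ± 72.6 against 22.2 ± 14.0 UMIs per 10000 (SD, n = 3; log2 fold change 2.92, SE 0.31, edgeR adjusted p = 0.00334), Tnfrsf17 (2.55), Runx2 (2.68), Ccr7 (2.01), Lgals1 (1.04), Lsp1 (0.91) and Xbp1 (0.64, at 174 ± 71.0 against 97.6 ± 40.3). They had less H2-K1 (log2 fold change -1.25), H2-DMa (-1.31), Ltbp3 (-1.35), Ly75 (-1.10), Il1a (-1.18), Txk (-1.44), Mpc2 (-0.81), Il23a (-2.25), Tnfsf9 (-0.86) and Ly6c1 (-0.72). Itgam (log2 fold change 2.35) and the interferon gamma gene Ifng (2.64) were higher as well, and Ifng varied widely, at 102 ± 163 against 10.7 ± 15.7. Ly6c1 rested on IgM cells, since in experiments 1, 2 and 3 it was at 71.9, 47.4 and 37.3 in IgA and 51.0, 55.1 and 41.8 in IgG2b cells. Tnfrsf17 passed against IgG2b cells but not against IgM cells. H2-K1 lies on chromosome 17 at 33996012 to 34000619, Tmem176b on chromosome 6 at 48833811 to 48845948 and Tnfrsf17 on chromosome 16 at 11313232 to 11320074 of GRCm38.p6.

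In all, 9 of 354 genes were higher and 10 lower in IgA cells, each in 3 of 3 experiments. In the plasma cell identity list Tnfrsf17 and Xbp1 were higher and Ly6c1 lower among 18, with 3 higher and 2 lower adjusted over the list alone. Among 47 cytokine and receptor genes 1 was higher and 3 lower, with 5 and 4 adjusted over the list alone. Members that passed as higher were Ccr7 of 26 mature B cell genes, Ccr7 and Itgam of 27 migration genes, Runx2 of 20 mucosal IgA-associated genes, Tnfrsf17 of 17 survival genes, Runx2 and Xbp1 of 40 transcriptional regulators, Ifng of 12 type 1 genes and Xbp1 of 11 unfolded protein response genes. Adjusted over the list alone the higher members numbered 1, 4, 2, 2, 2, 2 and 1 in these lists, and in the survival list Relb was lower. With an experiment left out all 19 kept their direction, but H2-K1, Tmem176b and Ifng alone passed without experiment 1, none without experiment 2, and H2-K1, Tmem176b, Tnfrsf17 and Runx2 alone without experiment 3. The fold change moved by over 1.5 times for Itgam without experiment 1 (log2 fold change 1.71) and for Runx2 without experiment 2 (1.99). Itgam passed among 4 myeloid markers, and S100a9 too adjusted over the list alone, with 504 S100a9 UMIs in IgA, 269 in IgM, 118 in IgG2b and 44 in naive cells. With edgeR, 0 members passed among 11 T cell, 5 Toll-like, 10 cell cycle, 11 germinal centre, 16 inhibitory receptor, 10 type 2, 2 NK and 2 erythroid or stromal genes; adjusted over the list alone, Il2rg of the type 2 list was higher. No list was called (smallest camera adjusted p = 0.607). The count of 19 was 3 without experiment 1, 0 without experiment 2, 5 without experiment 3 and 2 without the experiment block, while DESeq2 called 41, limma 20 and sums per mouse 27, where Mpc2 (edgeR adjusted p = 0.185) and Ly6c1 (0.295) did not pass and Il23a and Itgam were not tested. With library size alone 17 were higher and 7 lower, all 19 genes kept their direction, and Mpc2 (edgeR adjusted p = 0.0692), Tnfsf9 (0.0519) and Ly6c1 (0.177) did not pass. In that scaling 4 plasma cell identity genes were higher and 0 lower, and 3 cytokine and receptor genes were higher and 2 lower.

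**Figure D4:**
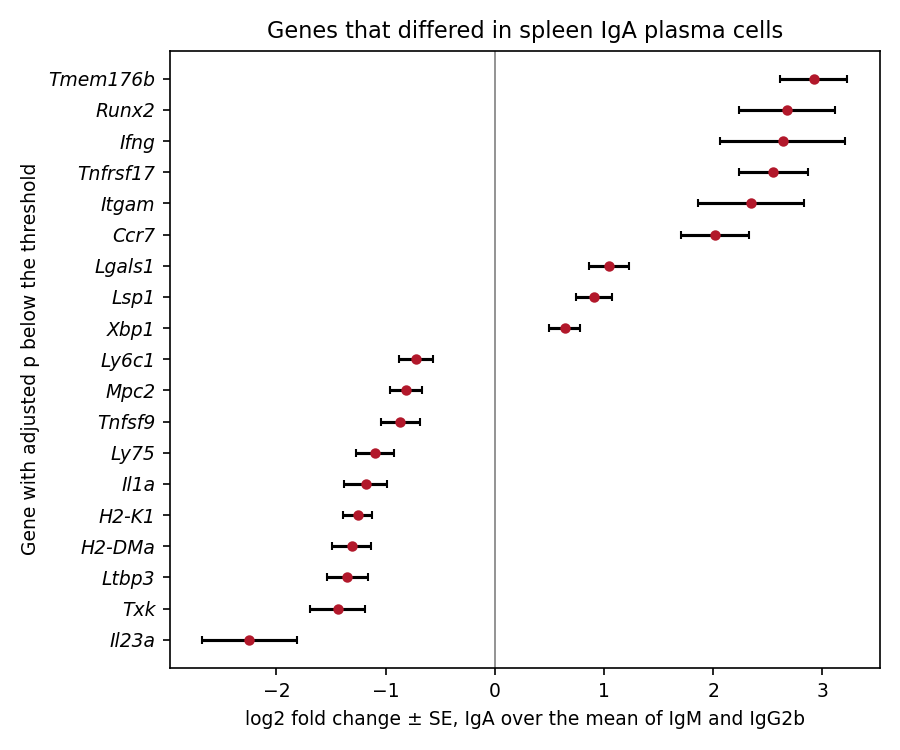
Fitted log2 fold changes (horizontal axis, points with SE bars) of the 19 genes (vertical axis) that differed between IgA cells and IgM and IgG2b cells together in spleen. They ran from -2.25 for Il23a to 2.92 for Tmem176b.

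On day 14 in lymph node, IgG1 and IgG2a/b cells specific for NP did not differ in any gene past the threshold. With edgeR 0 of 440 genes passed over 3 experiments, 16 had an unadjusted p under 0.05 and the smallest adjusted p was 0.142; DESeq2 called 2, limma 0, and sums per mouse 0 of 356, with 19 at an unadjusted p under 0.05. The genes with the smallest p included the inhibitory receptor gene Lilrb4a, with 5 UMIs in IgG1 cells and 155 in IgG2a/b cells (log2 fold change -4.20, SE 0.51, lower in 3 of 3 experiments), which passed adjusted over its list of 24 genes alone. The topoisomerase gene Top2a was at 34.5 ± 10.7 against 59.1 ± 17.7 UMIs per 10000 (SD, n = 3; log2 fold change -0.77, SE 0.18) and Mitf had 5 against 93 UMIs (-3.53, SE 0.63). The others of the first 10 were Fgl2 (log2 fold change -1.60), Ddit3 (-2.80), Ebf1 (-1.95), Sell (2.07), Cxcr3 (-1.26), Plac8 (-0.96) and Ccl5 (-3.59), none of which passed. Xbp1 (log2 fold change 0.09), Irf4 (0.20), Prdm1 (-0.27) and Sdc1 (-0.19) did not pass either. No list was called (smallest camera adjusted p = 0.684). Without day 14 experiment 2, which held only 41480 UMIs, edgeR called 12 genes, among them all of these 10 except Ebf1.

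On day 5, IgM cells were set against IgG2a/b cells, both sorted as specific for NP. All came from 1 experiment with 2 mice, so the ratios below have no replicate check over experiments. Igkc, the kappa light chain that the lambda1 gate selects against, had the highest ratio of UMIs per cell at 3.28, with 0.514 UMIs per cell in IgM cells (95% Poisson interval 0.388 to 0.667) and 0.157 in IgG2a/b cells (0.113 to 0.212). Cd79a was at 10.3 (9.71 to 10.9) against 5.73 (5.44 to 6.02), a ratio of 1.80, and Cd1d1, Ccr1, Sat1 and Ets1 had ratios of 2.05, 2.03, 1.86 and 1.78. Lowest were Rbpj, the effector of Notch signalling (0.302), Gclc (0.361), the uracil glycosylase gene Ung (0.391), the replication clamp gene Pcna (0.402, at 4.59 against 11.4 UMIs per cell), Traf3 (0.412), Eif2a (0.448), Bhlhe41 (0.473), Apex1 (0.473), Ccnd2 (0.476) and H2-DMb2 (0.495). The others of the highest were Pde3b (1.72), Ctla4 (1.70), Ly6d (1.70) and Stat6 (1.65). The median ratio over 205 genes was 0.821 per cell and 0.993 per 10000 UMIs, so these ratios are to be read against it. In mice 1 and 2 taken singly, Ly6d had ratios of 2.05 and 0.603 and Ctla4 2.53 and 0.810, on either side of 1. Other ratios that moved by over 1.5 times were those of Cd1d1 (1.20 and 3.38), Ung (0.735 and 0.138), Eif2a (0.759 and 0.196), Gclc (0.600 and 0.0556), Rbpj (0.151 in mouse 1), and in mouse 2 Pcna (0.228), Bhlhe41 (0.244), Ccnd2 (0.289) and H2-DMb2 (0.319). Without the 141 IgG2b cells of mouse 1, an alternative added after the data were seen, the median ratio was 0.669, and 2 of the 20 ratios moved by over 1.5 times, to 0.248 for Ung and 1.15 for Pde3b.

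IgG2a/b cells of day 14 were set against those of day 5 to follow time after immunization, with 3 experiments on day 14 and 1 on day 5, so no test was made. Ccl5, a chemokine of cytotoxic cells, had 485 UMIs on day 14 and 3 on day 5, a ratio of 83.6 per cell (95% exact interval 28.5 to 407). Slpi, a secreted protease inhibitor, was at 51.5 UMIs per cell (50.8 to 52.1) against 8.80 (8.45 to 9.16), a ratio of 5.85. Fgl2 (5.76), Klf7 (4.50), Iglc1 (4.25), Tmem176b (3.26), Ifng (2.997), Ccr7 (2.99), Ly6c1 (2.79) and Itgal (2.69) followed. Lowest were Ly6d at 0.132, Apex1 (0.228), Slamf6 (0.286), Eef2 (0.310), Ung (0.335), Myc (0.336) and Akt1 (0.353), with the replication genes Mcm2 (0.329), Mcm4 (0.343) and Mcm3 (0.346). The median ratio over 205 genes was 0.751 per cell and 0.803 per 10000 UMIs. Naive cells sorted with them had a median ratio of 1.99 per cell and 1.06 per 10000 UMIs, with means of 361 UMIs per cell on day 14 and 191 on day 5. Ccr7 had a log2 ratio per 10000 UMIs of 1.68 in naive cells and 1.67 in IgG2a/b cells. Without day 14 experiment 1, 7 of the 20 named ratios moved by over 1.5 times, to 3.73 for Slpi, 1.84 for Tmem176b, 1.71 for Ifng, 1.74 for Ly6c1, 1.13 for Itgal, 0.131 for Slamf6 and 0.218 for Mcm3, and 0 did so without either of the other day 14 experiments. Without the IgG2b cells of day 5 mouse 1, the median ratio was 0.624, and Ifng (1.81), Iglc1 (2.83) and Ung (0.213) moved by over 1.5 times.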

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

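Among the tests below, those that thinned cells to equal UMIs, left out abundant genes, set the Ighg1 share against day 14, compared naive cells between days or counted experiments of day 5 were chosen after the result was seen, and those on myeloid cells, on IgG1 cells in the IgG2b gate and on single mice were chosen before.

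In spleen, single mice lay far from the other mice of their gate for named genes in 18 groups, with levels as UMIs per 10000 UMIs. In all 91 groups were tested, among them median UMIs per cell of both tissues. Chance gives about 1 in 20 where groups are independent, which genes of the same mice are not. The only mouse of experiment 3 gave 11 of the 18. In IgA cells it stood at 117 for Ccr7 (others 4.77 to 35.2), 60.9 for Tnfsf9 (7.83 to 16.1) and 290.0 for Ifng (0.955 to 14.2). In IgM cells it stood at 11.1 for Runx2 (0.997 to 3.25), 21.4 for Ccr7 (5.70 to 9.58), 90.1 for Tnfsf9 (13.0 to 29.3) and 26.9 for Ifng (0.760 to 4.11). In IgG2b cells it stood at 17.7 for Ccr7 (0.540 to 5.61), 10.3 for Il23a (3.57 to 5.10), 98.8 for Tnfsf9 (14.9 to 28.6) and 31.6 for Ifng (0 to 3.06). A mouse of experiment 1 stood at 170 for Ly6c1 (7.89 to 73.4) and 29.9 for Txk (5.56 to 16.7) in IgA cells, and at 13.7 for Mki67 (74.9 to 110) and 14.3 for Mcm2 (42.3 to 54.1) in IgG2b cells. Other mice stood at 402 for Lsp1 in IgA cells (148 to 265), 153 for Xbp1 in IgM cells (69.0 to 90.4) and 74.96 for Ly6c1 in IgG2b cells (41.8 to 49.2). Without experiment 3 the log2 fold change of Ifng in IgA cells against the other gates was 2.36 in place of 2.64, and that of Ccr7 1.73 in place of 2.01; neither passed, as was so of 15 of the 19 genes there, 16 without experiment 1 and all 19 without experiment 2.

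IgA cells of spleen differed from the mean of IgM and IgG2b cells in 19 genes. These genes need not differ from each of the other gates, as Ly6c1 rested on IgM cells and Tnfrsf17 did not pass against IgM cells. In a window of 200 to 1000 UMIs per cell, fixed before its result was seen, 19 of 19 genes kept their sign and at least 0.5 of their log2 fold change, with a median size of 1.05 (SD 0.88 over genes) against 1.31 (SD 0.76), and 2 passed among 489 cells; because gates still differed in median UMIs there (392 in IgA, 437 and 440.5 in the others), every cell was then thinned to 200 UMIs, where 19 kept them at a median of 1.12 (SD 0.80) and 12 passed among 637 cells. Without cells that held a UMI of a myeloid list gene (37.3% of IgA, 42.2% of IgM and 41.8% of IgG2b cells), 18 of 18 genes other than Itgam kept them, at a median of 1.14 (SD 0.69) against 1.28 (SD 0.76), and 4 passed among 476 cells; why calls ended in these subsets was not tested. Without genes above 5% of all UMIs, 18 of the 18 genes other than H2-K1 passed again. That fit kept TMM, which already limits the weight of such genes, so this outcome was likely beforehand. With library size alone 16 of the 19 genes passed, and all 19 kept their direction. Cells with a myeloid list UMI held more Mzb1 than the rest of their gate, at 73.7 against 58.1 UMIs per cell in IgA cells. The values were 136 against 62.1 in IgM and 145 against 84.1 in IgG2b cells. That filter thus did not single out myeloid cells, and any myeloid cell without such a UMI stayed in. The values argue against cells with a counted myeloid list UMI as the whole cause. They do not decide on lower UMI totals. Thinning keeps the composition of each cell, the window still differed between gates, and both used the cells that gave the 19 genes. Nor do they decide on a few abundant genes, whose weight TMM already limits. A difference of antibody class remains a hypothesis found and tested on the same data.

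In the day 5 IgG2b gate, Ighg1 made up 50.9% (exact 95% interval 37.1% to 64.6%) of Ighg1 and Ighg2b UMIs, against 0.637% (0.0161% to 3.50%) in the day 14 IgG2b gate. Reads shared between these paralogs would give a like share on both days, so sharing alone is argued against. Of 17 cells with Ighg1 and 24 with Ighg2b, 2 had both, where independence gives 2.22, which is too few to say whether IgG1 cells entered the gate. Mouse 1 gave 27 Ighg1 UMIs in 141 cells and mouse 2 gave 1 in 43 cells, an 8.23-fold difference per cell, with Ighg2b at 8.51 and 34.9 UMIs per 100 cells. Both are day 5 mice, so the Ighg1 share was not common to the day 5 cells. With 1 mouse that held it and 1 that hardly did, its cause cannot be settled, and no biological explanation was tested.

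IgG2a/b cells differed between day 14 and day 5, with day 5 in 1 experiment, so an effect of that experiment or its mice on plasma cells cannot be told apart from time. A shift of all cells alike was tested in naive cells per 10000 UMIs, over the named genes with enough UMIs there. For Klf7, Tmem176b, Ly6c1 and Itgal, higher on day 14, the median log2 ratio in naive cells was -0.43 against 1.69 in plasma cells (SD over genes 0.13 and 0.34). This argues against such a shift as the whole cause for these 4 genes as a set. Naive counts were low, with 10 Ly6c1 and 19 Tmem176b UMIs on day 5, and their counting error was not included. Such a shift stays open for Ccr7, also higher, at 1.68 in naive and 1.67 in plasma cells. It also stays open for 6 genes lower on day 14, where the median, signed by the direction in plasma cells, was 0.55 (SD 0.74) against 1.55. These parts were made after the values of all genes together were seen, and time after immunization remains an open, untested explanation.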

How the results depend on the processing

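Alternatives with sums per mouse or sort plate, with naive cells kept, without IgG2b cells of day 5 mouse 1, and all those of the added comparisons were chosen after the data were seen. Over 241 named values, 2796 alternative values were computed: 2219 kept their direction and side of the threshold, 467 kept direction but lost the call, 22 gained one, 28 reversed and 60 moved by more than their spread. Counts are given in the order IgM against IgA (11), IgG2b against IgA (20), IgM against IgG2b (6) and IgA against both (19). DESeq2 called 35, 55, 21 and 41. Fits without the replicate block, whose pairing ran by experiment, called 0, 1, 0 and 2, and moved no other count by over 1.5 times. Only the gates compared gave 1 and 2 in the first 2, with fewer sums in the fit. Limma gave 6 in the first. Sums per mouse gave 20 in the first, sums per sort plate 19, 36 and 31 in the first, second and last, and fits with naive cells 5, 8, 2 and 6. Leaving out an experiment gave 0 to 1, 0 to 5, 0 to 4 and 0 to 5, with fewer samples. IgG1 against IgG2a/b (0) gave 2 with DESeq2 and 0 to 12 without an experiment. Plasma cells against naive cells gave 56 to 112 in spleen (109) and 64 to 79 in lymph node (113) without an experiment, and the day 5 test over mice (0) gave 7 with limma. Of 4 list calls in the planned comparisons, 0 held with an estimated correlation. Where not named, the cause was not tested. Leaving out cells with few UMIs, the filter on low counts or genes above 5% of all UMIs, or asking for 20 cells per sum, kept each count within 1.5 times.

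Reversed log2 fold changes were of genes that had not passed, except for Cd84 and Ccr6. In IgM against IgA, Irf4 was at -0.146 per sort plate and -0.0194 to 0.52 without an experiment, the lowest without experiment 3. Prdm1 was at -0.0602 there with library size alone, and Sdc1 at -0.23 to 0.0563 without an experiment, the highest without experiment 2. In IgG2b against IgA, Irf4 was at -0.0487 with library size alone, -0.0476 with limma, -0.173 per mouse and -0.0383 per sort plate. In IgM against IgG2b, Irf4 was at -0.00430 with DESeq2, -0.108 per sort plate and -0.14 to 0.27 without an experiment, and Xbp1 at -0.0220 with DESeq2, -0.0171 without the block, -0.0558 per mouse and -0.12 to 0.13 without an experiment, both lowest without experiment 3; Sdc1 was at -0.233 per sort plate. In IgA against both, Irf4 was at 0.0194 with library size alone and 0.0921 per sort plate. In IgG1 against IgG2a/b, Xbp1 was at -0.00163 without genes above 5% of all UMIs, -0.104 against IgG2b alone, -0.0522 per sort plate, -0.0341 without day 14 experiment 2 and -0.11 to 0.25 over experiments left out, and Prdm1 at -0.85 to 0.30, the highest without day 14 experiment 2. In lymph node plasma against naive cells, Cd84 and Ccr6 had passed as lower (log2 fold change -4.37 and -3.85, each lower in 1 of 2 experiments). They ran from -4.74 to 1.501 and from -4.65 to 2.99 without an experiment, the highest without day 14 experiment 1. Day 5 ratios without a mouse ran from 0.810 to 2.53 for Ctla4 and from 0.603 to 2.05 for Ly6d.

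Alternatives that gave no value were heavy chain genes kept in spleen, where the table held none; all those for IgM on day 14, since no cell was marked as such; the tool, filter, scaling, abundant gene, heavy chain, block, cells per sum and gates-compared alternatives of the comparisons without a test. Leaving out plates with both days was run as leaving out the experiment labelled with both days. Depth limits the results of both tissues, with a median of 342 UMIs per cell in spleen and 588 in lymph node. Of the lymph node experiments, day 14 experiment 2 had the lowest median, at 295 UMIs per cell, and the fewest cells, 83. Naive cells of day 5 had a median of 155.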

Other observations

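Among the results here, the plasma cell comparison in lymph node, the day 5 test over mice, the tissue comparison and the splits were chosen after the results were seen, other than those of spleen plasma cells against naive cells and those of IgA against the other gates that were not limited to as many parted mice.

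Plasma cells of day 14 lymph node differed from naive cells of the same 2 experiments in 113 of 435 genes, 73 higher and 40 lower (edgeR). Mzb1 was at 1394 ± 426 UMIs per 10000 against 99.6 ± 57.3 (SD, n = 2; log2 fold change 4.67, SE 0.26) and Xbp1 at 122 ± 23.6 against 3.69 ± 0.292 (5.77, SE 0.35). Slpi was at 499 ± 81.4 against 0.870 ± 1.23 (log2 fold change 9.16, SE 0.64), and Ifng rose by 6.14 on the log2 scale, Prdm1 by 4.43, Sdc1 by 3.27 and Irf4 by 1.20. The rise of Sdc1 is again not independent of the sort by CD138. Eaf2 had 0 UMIs in 78 naive cells and was at least 6.27-fold higher, and Fgl2 at least 5.57-fold, against a floor of 3 counts over the group. Sell fell by 6.10, Pax5 by 5.87 and Cd72 by 6.07. Of 18 plasma cell identity genes 12 rose and 2 fell, with 13 and 2 adjusted over the list alone (camera adjusted p = 0.00140, and adjusted p = 0.393 with an estimated correlation). Of 32 mature B cell genes 2 rose and 14 fell, with 3 and 17 adjusted over the list alone (camera adjusted p = 1.71e-05, and adjusted p = 0.545 with an estimated correlation). Of 13 cell cycle genes 5 rose, among them Top2a, Mki67, Aurkb and Ccnd2, and 6 adjusted over the list alone (camera adjusted p = 0.0344, and adjusted p = 0.393 with an estimated correlation). Of markers of other cell types, Cd8a (log2 fold change 3.53) and Cd40lg (0.95, at a higher level in 1 of 2 experiments) were higher and Cd2 (-3.93) and Icos (-2.26) lower among 14 T cell genes, and the granzyme gene Gzma (2.80) was higher among 5 NK genes, in each case also adjusted over the list alone; none of 5 myeloid and 2 erythroid or stromal genes passed. With library size alone 0 T cell genes were higher and 3 lower, and Cd8a (edgeR adjusted p = 0.0814), Cd40lg (0.539), Irf4 (0.175) and Ccnd2 (0.108) did not pass. With library size alone 44 genes were higher and 72 lower, since all genes moved by a median of -0.62 on the log2 scale, and all 113 kept their direction; 11 plasma cell identity and 3 cell cycle genes were higher there, and 20 mature B cell genes lower and 1 higher; the count was 64 without day 14 experiment 1.

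Levels of the 2 tissues stood side by side without a test, since tissue, antigen gate and experiments differed. Xbp1 was at 120 ± 51.3 UMIs per 10000 in spleen plasma cells (n = 3) and 122 ± 23.6 in day 14 lymph node plasma cells (n = 2), Ly6c1 at 74.3 ± 12.8 and 79.7 ± 27.9, and Slpi at 19.3 ± 4.78 and 499 ± 81.4. The IgM against IgG2b difference was compared between day 5 lymph node and spleen over mice with both gates, 2 and 4 of them, with more Ighg1 than Ighg2b UMIs in the IgG2b cells of day 5 mouse 1, and 0 of 311 genes passed with edgeR, 17 at an unadjusted p under 0.05. On day 5 alone, a test of IgM against IgG2a/b over the 2 mice called 0 of 356 genes with edgeR, 14 at an unadjusted p under 0.05, 0 with DESeq2 and 7 with limma. In it, cell cycle genes were lower as a list of 11 (camera adjusted p = 0.00612, and adjusted p = 0.964 with an estimated correlation), with no member passing, also adjusted over the list alone.

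Other splits of the same sums were fitted to see how often they gave as many genes. For IgA against the other gates, 1 of 84 splits of the experiment sums gave as many as the real 19, the real one itself, and the highest other gave 12, also among the 27 that part as many pairs, while 3 splits could not be fitted; that comparison was chosen after the data were seen, for which the splits make no allowance. Spleen plasma cells against naive cells gave 109, reached by 1 of 100 splits drawn from 220, with 33 the highest other. Over mice, splits that part as many mice as the real one were compared. For IgM against IgA the real 20 was reached by 1 of 64 splits (highest other 16). For IgG2b against IgA the real 27 was reached by 1 of 100 drawn from 128 (highest other 16), and for IgM against IgG2b the real 4 by 1 of 48 (highest other 2). Each real count was the highest among its splits. Sums per mouse were added after the data were seen, for which the splits make no allowance, so chance is not excluded. For IgA against the other gates the real 27 was reached by 1 of 100 drawn from 3888, with 22 the highest other. Drawn splits that mostly part fewer mice gave at most 6, 3, 2 and 1 genes in these comparisons, 1 of 100 as many as the real one. Over experiments these comparisons have only 10 splits, too few for a share under 0.05; the real counts were 11, 20 and 6, 1 split each reached them, and the highest other gave 0. For IgG1 against IgG2a/b on day 14 the real count was 0, so every split was as large, all 10 over experiments and, over mice, the 95 of 100 drawn that could be fitted, with 3 genes the highest other. The 30 genes that were the highest other over experiments came from splits that parted day 14 experiment 2 alone, so that these calls rested on 1 pair of sums; the 4 splits that part as many pairs as the real one gave 0.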
